A study of Caenorhabditis elegans with 2 samples.

How the data were processed

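ChIP-seq against LIN-35 was done in 2 biological replicates of whole young adult worms, per the labels, with a library size range of 150 to 350 in the labels, which give no unit. The labels name the antibody by the target lin-35 and describe the experiment as directed at an eGFP fusion, so it is not settled here whether the tag or the protein was the epitope. The deposited files are 8 peak lists, 4 on each of the builds ce11 and ce10. For each build there is a list for replicate 1, a list for replicate 2, a pooled list and a list called optimal IDR thresholded (irreproducible discovery rate, a measure of how well peak ranks repeat between replicates). Per the deposited text notes, the replicate and pooled lists were made from the alignments together with a control library, and the thresholded list from the pooled and replicate lists. The control library was not analysed here. The aligner, the peak caller, their versions and the IDR cutoff are not given in the sources used here.

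The signal of each peak is the authors' own value, in the signal column of the deposited narrowPeak lists, and how it was scaled is not stated. A second column holds the −log10 of a q value for each peak in the deposited lists, by the convention of that format. It ran from 2.56 to 3.04 in the ce11 thresholded list and was not used to rank peaks. The files give neither read counts nor depth, so the depth of each sample is unknown, and intervals printed with shares cover the counting of peaks or genes only. Several facts about the lists limit what they can show. The ce11 lists of replicate 1 and of the pooled data stop at exactly 30000 lines, while that of replicate 2 has 18226, and these lists hold background as well as peaks, per the deposited text notes. The median signal at shared peaks was 26.1 in replicate 1 and 11.5 in replicate 2, so signal values were not compared in size between replicates. In the ce11 thresholded list 3 peaks repeated the interval of another with a different summit, and each line was counted as a peak.

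Peaks on ce11 were set against the WBcel235 annotation of Ensembl release 115 and its genome sequence, after checking that all peak ends lay within the chromosome lengths. Coordinates are 1-based. A gene was called bound when a thresholded summit lay from 1000 bp upstream to 300 bp downstream of any of its transcript starts, and a peak could be assigned to several genes. The share of summits in such windows was compared with the share of genome bases by an exact binomial test, and peaks per chromosome with the share of protein-coding genes by the same test. The 18 gene lists, 15 written by hand and 3 taken by symbol pattern, were tested with Fisher's exact test against all other protein-coding genes, and 6 listed symbols matched no gene. Motifs were sought on both strands in windows of 100 bp either side of the summit. They were compared by Fisher's exact test with 5 control windows per peak, matched within 2 percentage points of GC, from promoter windows without a thresholded peak. Adjusted p-values are Benjamini-Hochberg, all tests are two-sided and 95% intervals of shares are exact (Clopper-Pearson). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

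The tests, the gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes the genes with a promoter-window summit of the 20 highest thresholded peaks, up to 4 bound members of highest signal in each list, all 8 DREAM complex members, and mex-5, lin-35 and unc-119 reported apart because the transgene carries their sequences. Members named beyond the 4 of a list, and genes named for sharing a peak, were chosen after their values were seen. Other settings fixed at that time were the ce10 lists, other overlap rules, each replicate's own 550 highest peaks, the 275 highest peaks, the 1000 or 3000 highest pooled peaks, other promoter windows, the nearest start, other expected shares and backgrounds, a circular shift of bound states along the gene order with 10000 draws, other motif windows, controls and motifs. Settings chosen after seeing the data were nuclear peaks only, promoter peaks only for the chromosome shares, controls matched on CG dinucleotides, and leaving out ribosomal protein promoter peaks or lin-35. The plan itself was in conflict on lin-35. It said that the transgene's genes would be tested in no list, but the DREAM list fixed with it held lin-35. The list was tested as written, and the result without lin-35 is given beside it.

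The code was tested on simulated data. Of 500 summits placed 100 bp upstream of a start, 500 were assigned to its gene. With the mitosis list bound at 25% among 19985 genes, 99 of 100 simulations called it, and 3 of 100 random draws called any list. With the E2F motif planted in 15% of 550 windows, 100 of 100 simulations found it, and 3 of 100 without it passed an unadjusted p of 0.05.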

Results

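LIN-35, the pocket protein of Caenorhabditis elegans and its relative of the retinoblastoma tumour suppressor, was mapped on the genome by chromatin immunoprecipitation and sequencing (ChIP-seq). Pocket proteins do not bind DNA themselves. They act with E2F-DP proteins and, in the DREAM complex, with LIN-54, which recognises a short element found in cell cycle promoters. The worms were mixed-sex young adults of strain YL468, whose transgene puts a LIN-35:GFP:FLAG fusion under the promoter of mex-5, a gene used in the germ line. Whole animals were used, so chromatin of germ line and soma entered each sample together. How far the signal came from either is unknown, because the epitope is not settled. The 2 samples were biological replicates 1 and 2 of a single group, and the data hold no second condition to compare them with. The files give peaks and not reads, so the sequencing depth of the samples is unknown. Coordinates are on build ce11 (WBcel235) unless ce10 is named.

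The question put to the peak lists was where in the genome the LIN-35 ChIP signal was enriched and at which genes. The strongest nuclear peak lay upstream of rpl-3, a large-subunit ribosomal protein gene (III:3867385-3867747), at a signal value of 402 in the pooled list, 299 in replicate 1 and 108 in replicate 2. It was followed by the promoters of cdc-48.1, an AAA ATPase that extracts ubiquitinated proteins (II:10563426-10563721, signal 291), and of tasp-1, a threonine aspartase, whose peak also fell in the promoter window of K01G5.10 (III:10759080-10759402, signal 282). Next came rpl-35, another large-subunit ribosomal protein gene (247), sec-61.G, a subunit of the endoplasmic reticulum translocon, with its neighbour F32D8.13 (231), Y39B6A.43 (156) and the alpha-tubulin gene tba-2 (149). All 7 of these peaks were also among the highest peaks of each replicate's own list. The other 13 of the 20 highest peaks were mitochondrial. They included the highest of all, MtDNA:4362-5043 with a signal of 478. Some of these summits fell in the promoter windows of COX3, ND1 and the genes annotated as WBGene00000829, WBGene00010960, WBGene00010961, WBGene00010963, WBGene00010964, WBGene00010965, WBGene00010966 and WBGene00010967.

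The authors' thresholded list, made from both replicates, held 550 peaks on ce11, with a median signal of 34.96 and a range of 24.8 to 478. The signal is the authors' own value for each peak and its scale is not given, so it is used here to describe and rank peaks within a list, and between the replicates only in a correlation. Peak widths had a median of 356 bp, and 83.8% of the peaks had exactly that width. Of the 550 peaks, 27 (4.91%) were mitochondrial and 523 were nuclear. The ce10 list held 561 peaks. The 550 peaks were the 550 of highest signal in the pooled list of 30000, so the authors' threshold acted as a cutoff on that list.

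Replicate agreement was measured as the share of the thresholded peaks that were also among the 550 highest of each replicate's own list. Replicate 1 held 435 of them (79.1%) and replicate 2 held 322 (58.5%). Both held 241, or 43.8% (95% exact interval 39.6 to 48.1), and 34 peaks were in neither set. These shares measure overlap with a list that was itself made from both replicates and ranked by pooled signal. The median signal at shared peaks was 26.1 in replicate 1 and 11.5 in replicate 2, so replicate 1 may weigh more in that ranking. How far this set its larger share was not tested. The highest 550 of the 2 replicates were not compared directly with each other. The peaks of rpl-3, cdc-48.1 and tasp-1 were in both sets, as were all 5 peaks at DREAM complex genes and 15 of the 21 peaks at ribosomal protein genes. The peak shared by sas-4, a centriole assembly gene, and F10E9.11 was in neither. With whole lists in place of the highest 550, 530 of the 550 peaks (96.4%) overlapped a peak in both replicates, and with 3 times as many peaks per replicate the share was 76.2%. Across those 530 peaks the signal values of the replicates had a Pearson correlation of 0.51 on the log2 scale and a Spearman correlation of 0.29. Among the 504 nuclear peaks these were 0.33 and 0.19. These peaks were chosen for a high pooled signal, which narrows the range and lowers such correlations. Over the 6431 nuclear peaks of the whole pooled list that overlapped both replicates' lists, the values were 0.50 and 0.36. Peaks are not independent replicates, so no p-value is given.

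**Figure D1:**
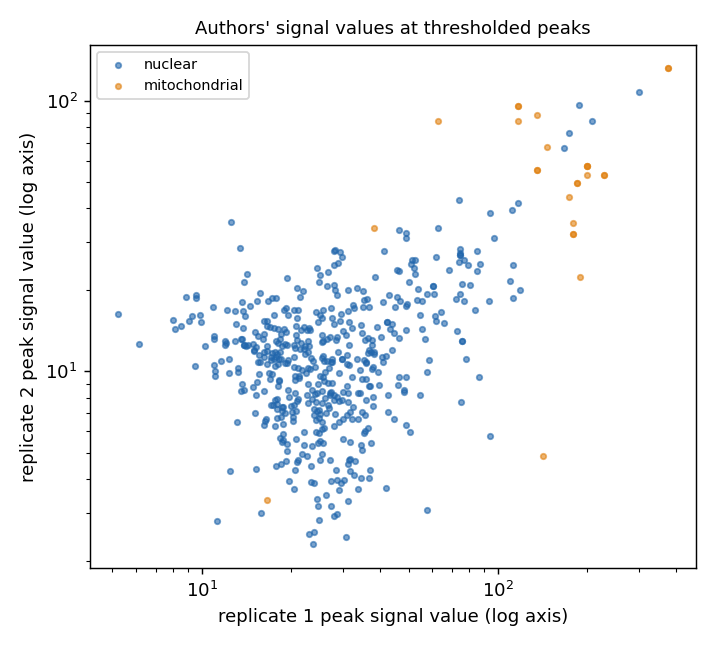
Each point is a thresholded peak, placed by the authors' signal value of the overlapping peak in replicate 1 (x, log axis) and in replicate 2 (y, log axis), for the 530 peaks found in both. Nuclear peaks are blue and mitochondrial peaks orange; the Spearman correlation was 0.29 over all points and 0.19 over the 504 nuclear ones.

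LIN-35 peaks were concentrated at gene starts. Of the 550 summits, 403 (73.3%, 95% exact interval 69.4 to 76.9) fell between 1000 bp upstream and 300 bp downstream of a protein-coding transcript start, against 28.1% of genome bases (two-sided exact binomial test, p = 2.2e-106). Among nuclear peaks the share was 381 of 523 (72.8%). Of these 381 summits, 321 (84.3%) were intergenic, 25 lay in a UTR, 24 in an intron and 11 in a coding exon. The peaks marked 553 protein-coding genes as bound, 2.77% of the 19985 annotated. A single gene was assigned to 219 of the nuclear promoter peaks, 2 genes to 150 and 3 genes to 12. In 143 of the 381 (37.5%) the genes stood on both strands, so the peak could not be given to either gene of such a pair.

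Chromosomes I and III held more peaks than their share of genes, and chromosomes V and X fewer. Chromosome X, which is largely silent in the germ line, had 36 of the 523 nuclear peaks (6.88%, 95% exact interval 4.87 to 9.40) against 13.7% expected from its protein-coding genes (two-sided exact binomial test with Benjamini-Hochberg adjustment over 6 chromosomes, adjusted p = 6.9e-06). Chromosome I had 110 peaks (21.03% against 14.4%, adjusted p = 9.5e-05), chromosome III had 108 (20.7% against 13.2%, adjusted p = 8.6e-06) and chromosome V had 92 (17.6% against 25.004%, adjusted p = 9.5e-05), all by the same exact test. Chromosomes II (89 peaks, 17.02% against 17.3%) and IV (88 peaks, 16.8% against 16.4%) did not pass the test (adjusted p = 0.954 for each, exact test). The peaks on X also lay elsewhere. On X, 27 of 36 (75%, 95% exact interval 57.8 to 87.9) were outside promoter windows, against 115 of 487 autosomal peaks (23.6%, 19.9 to 27.6), an odds ratio of 9.70 (95% interval 4.26 to 24.0, Fisher's exact test, p = 6.9e-10). This last comparison was chosen after the data were seen. Counted over promoter peaks alone, X held 9 of 381 (2.36%). The call for X did not hold in the 275 peaks of highest signal, where its share was 9.60% (exact test, adjusted p = 0.0977). The call for V did not hold in the exact test when the expected share came from chromosome length (20.9% expected, adjusted p = 0.101) or from the pooled list (18.3% expected, adjusted p = 0.734).

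**Figure D2:**
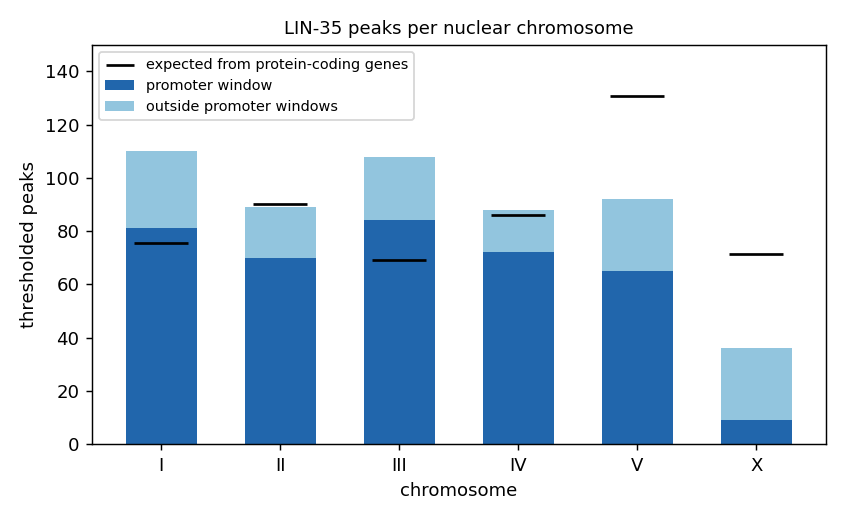
Bars give the number of thresholded peaks on each nuclear chromosome, split into peaks inside (dark) and outside (light) promoter windows; black lines give the number expected from each chromosome's share of protein-coding genes. X held 36 peaks against 71.5 expected, and 27 of the 36 lay outside promoter windows.

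Genes of the DREAM complex were themselves among the bound genes. Of its 8 members, 5 had a thresholded peak at the promoter (62.5%, odds ratio 59.1, 95% interval 11.5 to 381, Fisher's exact test, adjusted p = 5.0e-06 over 18 lists). The peak at lin-9 (III:8904095-8904450) had a signal of 76.0, or 50.01 in replicate 1 and 21.5 in replicate 2. The peak upstream of lin-54, the DNA-binding subunit, had a signal of 75.5 and lay in the window of rpl-12 as well (IV:13240620-13240763). The peaks at lin-53, a histone chaperone also found in other chromatin complexes (I:9619801-9620156), and efl-1, the E2F subunit (V:16965720-16966075), had signals of 70.2 and 62.0. They were shared with nra-2 and fbxa-90. The lin-35 promoter itself had a peak of signal 34.9. The remaining members dpl-1, the DP subunit, lin-52 and lin-37 had their best promoter peaks only at ranks 5088, 7469 and 7904 of the pooled list. Without lin-35, whose sequence the transgene carries, 4 of 7 members were bound (odds ratio 47.2, Fisher's exact test, adjusted p = 1.1e-04).

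Genes for DNA replication and chromosome segregation were bound more often than other genes. Of 30 replication genes, 6 were bound (20%, odds ratio 8.87, adjusted p = 6.6e-04, Fisher's exact test). They were pcn-1, the sliding clamp (signal 69.7; IV:4049621-4049735), mcm-2 of the replicative helicase (50.4; II:12006676-12007031), rfc-4 of the clamp loader (49.7; III:6971917-6972272), the origin licensing gene cdc-6 (46.8; I:4270436-4270791), mcm-4 (28.9) and mcm-7 (26.9). The rfc-4 peak was shared with eef-1A.1, a translation elongation factor, and the cdc-6 peak with acin-1. Of 51 mitosis and kinetochore genes, 13 were bound (25.5%, odds ratio 12.3, adjusted p = 7.9e-09, Fisher's exact test). The strongest were hcp-3, the centromeric histone H3 variant (signal 100.98; 62.9 in replicate 1 and 33.9 in replicate 2; III:9617020-9617221), and knl-3, an outer kinetochore protein (79.8; V:1868712-1868889, shared with T10B5.3). They were followed by hcp-4, the worm CENP-C (46.6; I:3866467-3866822, shared with the glycolytic gene pgk-1), and kbp-4, another kinetochore protein (46.2; III:1080573-1080928, shared with par-2 and rab-18). Of the 6 replication peaks, 4 were in the highest 550 of both replicates, and of the 13 mitosis peaks, 7 were. Replicate 2's own list gave 8 of 30 replication genes (odds ratio 15.8, exact test, adjusted p = 1.4e-06) and replicate 1's gave 4 of 30 (odds ratio 5.55, adjusted p = 0.0377). The mitosis list fell to 6 of 51 with the window of 500 bp upstream to 100 bp downstream (odds ratio 5.80, exact test, adjusted p = 0.0045) and to 6 of 51 by nearest start (odds ratio 5.15, adjusted p = 0.0065).

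Ribosomal protein genes formed the list with the most bound members. Of 78 cytosolic ribosomal protein genes, 22 were bound through 21 peaks (28.2%, 95% exact interval 18.6 to 39.5, odds ratio 14.3, adjusted p = 2.1e-15, Fisher's exact test). After rpl-3 and rpl-35 the strongest were rpl-24.2 (signal 137; I:9669163-9669378) and rpl-15 (109; IV:654821-655015, shared with K11H12.8). The list was taken by symbol, and the role of each member was not checked. Against genes with a pooled peak as background, the odds ratios were 24.4 for DREAM, 4.18 for replication (exact test, adjusted p = 0.0290), 6.21 for mitosis and 6.23 for ribosomal protein genes, all still past the threshold. With the peaks at these promoters left out, a choice made after the data were seen, 6 of the other 17 lists passed the test.

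A further 3 lists of germline regulators passed by a narrow margin, each at an adjusted p of 0.0436 (Fisher's exact test). Germ granule and germline RNA regulators had 4 of 34 genes bound (odds ratio 4.71): the RNA helicase gene cgh-1 (signal 57.2; III:7498400-7498755), the RNA-binding spn-4 (34.1, shared with spe-39), the zinc finger gene mex-1 (27.3) and the Nanos relative nos-3 (25.12). Small RNA pathways had 4 of 36 (odds ratio 4.42): rde-2 (46.6, shared with pfd-6), nrde-2 of nuclear RNA interference (37.8, shared with atad-3), mut-15 (34.6, shared with the fibrillarin gene fib-1) and ekl-1 (27.1). Germline chromatin regulators had 3 of 19 (odds ratio 6.62): mes-2, the worm enhancer of zeste (47.1; II:14383663-14384018), the chromodomain gene mrg-1 (34.1, shared with spcs-2) and the histone H3 lysine methyltransferase gene set-2 (29.5). None of the 3 calls held against genes with a pooled peak as background (exact test, adjusted p = 0.213, 0.204 and 0.204 in the order given) or when bound states were shifted along the gene order (permutation test, adjusted p = 0.0996, 0.158 and 0.0996). From replicate 2's own list, small RNA pathways had 1 of 36 bound (odds ratio 1.22, exact test, adjusted p = 0.924), and from replicate 1's, germ granule regulators had 3 of 34 (odds ratio 3.49, adjusted p = 0.144). The narrower promoter window (500 bp upstream to 100 bp downstream) ended the calls for germ granule regulators and small RNA pathways (adjusted p = 0.124 and 0.354, exact test). The wider one (2000 to 500 bp) ended those for germ granule and chromatin regulators (adjusted p = 0.0729 for each, exact test), and assignment to the nearest start those for small RNA pathways and chromatin regulators (adjusted p = 1 and 0.234, exact test). None of the 3 passed in the 275 highest peaks (adjusted p = 0.805, 0.365 and 0.750, exact test), and all 3 passed with the 1000 highest pooled peaks (adjusted p = 0.0025, 0.0030 and 0.0239, exact test) and with the 3000 highest (adjusted p = 1.9e-04, 8.4e-04 and 0.0026, exact test). Replicate 2's own list also gave 5 of 34 germ granule regulators (odds ratio 7.45, exact test, adjusted p = 0.0029) and 4 of 19 chromatin regulators (odds ratio 11.5, adjusted p = 0.0028).

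The remaining 11 lists did not pass. DNA repair had 3 of 32 genes bound (adjusted p = 0.130, Fisher's exact test): brc-1, the worm BRCA1 (32.5), the checkpoint clamp gene mrt-2 (30.7) and the end-joining ligase lig-4 (25.9). Meiosis had 2 of 29 (adjusted p = 0.382, exact test), the meiotic cohesin genes rec-8 (36.7) and coh-3 (29.6), whose peak was shared with the kinesin gene bmk-1. Cell cycle kinases and cyclins had 1 of 20 (adjusted p = 0.703, exact test), the inhibitory kinase gene wee-1.3 (27.5); the best promoter peaks of cyb-1, cdk-1 and cki-2 stood just under the authors' threshold, at pooled ranks 591, 714 and 843, and these genes were chosen after their values were seen. With the 1000 highest pooled peaks that list had 4 of 20 bound (adjusted p = 0.0252, exact test), and with the 3000 highest it had 6 of 20 (adjusted p = 0.0163, exact test). With 3000, DNA repair had 11 of 32 (odds ratio 4.98, adjusted p = 4.1e-04, exact test) and meiosis 10 of 29 (odds ratio 4.999, adjusted p = 6.8e-04, exact test). Histones had 4 of 81 (adjusted p = 0.520, exact test): the H2A.Z gene htz-1 (52.6, shared with wapl-1), his-37 (47.6), and his-67 with his-68 through a single peak (29.2). From replicate 2's own list histones had 7 of 81 bound (odds ratio 4.10, exact test, adjusted p = 0.0064), and from replicate 1's 2 of 81 (odds ratio 0.908). No gene was bound among 11 other synMuv genes, 13 cell death genes, 13 muscle, 14 intestine, 20 neuron and 17 cuticle markers or 31 major sperm protein genes (adjusted p = 1 for each, exact test). The muscle, intestine, neuron, cuticle and sperm lists together had 0 of 95, which allows a share of up to 3.81% (95% exact interval), above the 2.77% of all genes (Fisher's exact test, p = 0.117), so a lack of binding there was not shown.

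**Figure D3:**
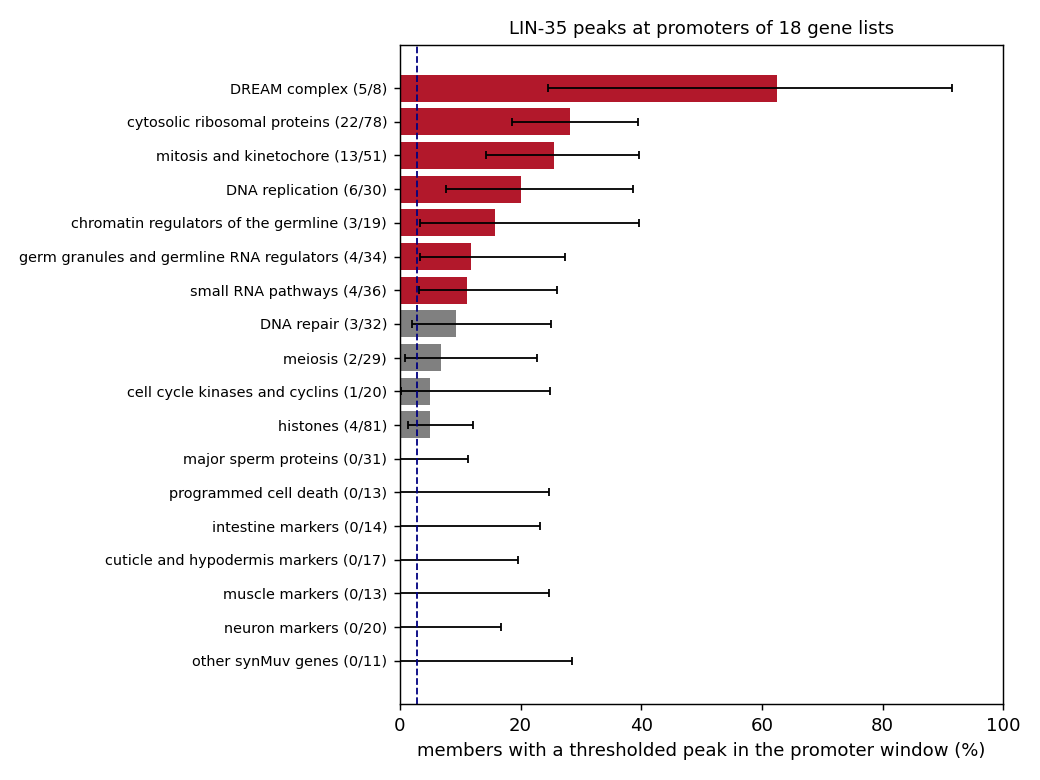
Bars give the percent of each gene list with a thresholded peak summit in the promoter window (bound and total members in parentheses), with exact 95% intervals as black lines; red bars passed an adjusted p of 0.05. The dashed line marks the 2.77% of all protein-coding genes that were bound, and the DREAM list stands highest at 62.5%.

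The E2F motif TTTSSCGC (S is C or G) was found within 100 bp of 77 of the 550 summits (14%, 95% exact interval 11.2 to 17.2) and in 108 of 2750 GC-matched promoter windows without a thresholded peak (3.93%, 3.23 to 4.72). The odds ratio was 3.98 (2.88 to 5.47, Fisher's exact test, adjusted p = 3.3e-16 over 4 strings). The CHR-like element TTYGAA (Y is C or T), of the kind bound by LIN-54, was in 325 windows (59.1%) against 46.6% of controls (odds ratio 1.65, 1.37 to 2.00, Fisher's exact test, adjusted p = 1.9e-07). Its odds ratio was 1.81 with 50 bp either side, 1.32 with 200 bp and 1.26 without GC matching (Fisher's exact test, p = 5.6e-09, 0.016 and 0.015). The E2F motif was unevenly spread over the bound genes. In the 24 promoter peaks of DREAM, replication and mitosis genes, E2F motifs were in 12 (50%, 95% exact interval 29.1 to 70.9), including those of lin-9, lin-54, lin-53, efl-1, pcn-1, hcp-3 and knl-3. In the 21 ribosomal protein peaks there was 1 (4.76%), the peak shared by rpl-12 and lin-54. With that shared peak left out of both classes, the shares were 11 of 23 (47.8%) and 0 of 20 (95% exact interval up to 16.8%; Fisher's exact test, adjusted p = 7.9e-04 over 3 strings). The CHR-like element was in 20 of the 23 and 13 of the 20, a difference that did not pass (Fisher's exact test, adjusted p = 0.148). Nor did the E2F share of ribosomal protein peaks differ detectably from that of other promoter peaks (odds ratio 0.231, Fisher's exact test, adjusted p = 0.302). These class comparisons were chosen after the data were seen. Nuclear promoter peaks carried the CHR-like element in 251 of 381 (65.9%), X peaks outside promoters in 9 of 27 (33.3%) and autosomal peaks outside promoters in 51 of 115 (44.3%).

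The strings read backwards, which have the same composition, served as a check. The reversed CHR-like element AAGYTT was rarer at peaks than in controls (27.1% against 32.8%, odds ratio 0.760, adjusted p = 0.0091, Fisher's exact test), but not when controls were also matched on CG dinucleotides (27.1% against 27.8%, odds ratio 0.966, exact test, p = 0.754). The difference also did not pass the exact test against the peaks' own flanks (p = 0.137) or with replicate 1's own list (p = 0.072). The reversed E2F string CGCSSTTT was also more frequent at peaks (6% against 2.22%, odds ratio 2.81, Fisher's exact test, adjusted p = 1.9e-05), so the excess was not limited to the motif itself. Peak windows held 10.7 CG dinucleotides on average and GC-matched controls 7.59. With controls matched on CG dinucleotides too, chosen after the data were seen, the E2F share was 14% against 5.91% (odds ratio 2.59, Fisher's exact test, p = 7.6e-10). The reversed E2F share was 6% against 2.66% (odds ratio 2.33, exact test, p = 1.7e-04). The excess of the motif was thus only slightly above that of its reversed string. The CHR-like share was 59.1% against 49.1% (odds ratio 1.496, exact test, p = 2.1e-05).

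**Figure D4:**
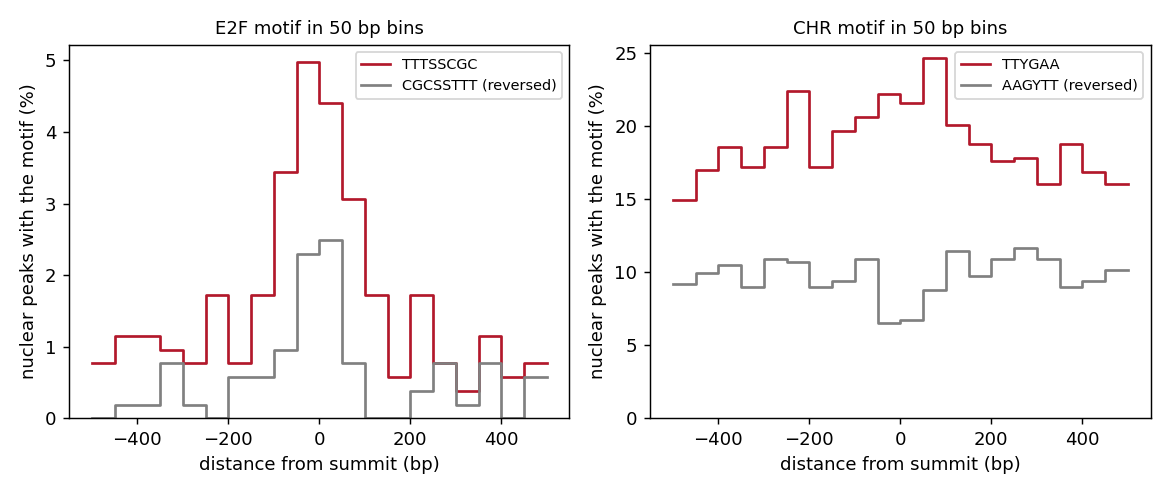
Lines give the percent of the 523 nuclear peaks with a motif in each 50 bp bin, by distance from the summit in bp (x), for the E2F motif (left) and the CHR-like element (right), with the reversed strings in grey. The E2F motif reached 4.97% in the bin just left of the summit against 0.765% in the leftmost bin, and the reversed E2F string also rose at the summit. The CHR-like element was not highest at the summit. It was in 22.2% just left of it, 24.7% at 50 to 100 bp right of it and 22.4% at 250 to 200 bp left of it. Its leftmost bin had 14.9%.

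Genes whose sequence the transgene carries stand apart, because extra copies of a sequence can add reads. The mex-5 promoter had a thresholded peak (IV:13353311-13353666, signal 36.7, with 15.8 in replicate 1 and 19.4 in replicate 2) that also lay in the window of rec-8. The peak at the lin-35 promoter (I:5807347-5807702) had signals of 20.9 and 14.8 in replicates 1 and 2 and was shared with vps-51, a vesicle tethering gene. The gene unc-119, used to mark the transgene, was not bound, with its best promoter peak at rank 10456 of the pooled list. The labels do not give the ends of the transgene's sequences, so signal from it and from the native loci was not separated.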

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

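All alternatives in this part were planned, except nuclear peaks only, promoter peaks only for the chromosome shares, CG-matched controls, and leaving out ribosomal protein promoter peaks or lin-35. No paired analysis was possible because the 2 replicates form a single group. The promoter share passed its test in all 8 alternatives (52.7% to 80.7%, and without replicate 1 or 2, 62.9% and 73.1%). The E2F share passed in all 12 (7.77% to 25.27%). The reversed E2F string was also more frequent than in controls in each setting where it was counted. Odds ratios of the motif and the reversed string were 4.81 and 4.78 with 50 bp either side. They were 4.42 and 4.32 with the peaks' own flanks as controls, and 5.18 and 3.98 in the 275 highest peaks. So these passes are not particular to the motif. The share of peaks held by both replicates was 38.0% with summits within 100 bp, 76.2% with 3 times as many peaks and 96.4% with whole lists, where the larger sets set the rise. The X share stayed below expectation in all 9 alternatives but not past the threshold in the 275 highest peaks (9.60% against 13.7% expected); the cause was not tested. The CHR-like share lost its call with the 3000 highest pooled peaks (52.9% against 51.3%, Fisher's exact test, p = 0.119); the cause was not tested. The count of 7 lists was 4 in the 275 highest peaks, 4 against genes with a pooled peak and 4 under the circular shift, 6 to 7 without a replicate, 5 with either other promoter window or the nearest start, and 8 and 10 with the 1000 and 3000 highest pooled peaks; the cause was not tested. The DREAM, replication, mitosis and ribosomal protein calls were not lost in any of them, apart from the ribosomal list when its own peaks were left out, but their odds ratios ranged widely (15.8 to 85.0, 4.18 to 15.8, 5.15 to 16.2 and 6.23 to 22.5). Several uncalled results changed direction, and the cause was not tested. Chromosome II went above expectation in the 275 highest peaks (18%), by length and by the pooled list (17.02% each) and over promoter peaks (18.4%). Chromosome IV went below it in the 275 highest peaks (15.6%) and by length and the pooled list (16.8% each), with 14.3% to 17.4% without a replicate. The histone odds ratio was 0.908 to 4.10 without a replicate and 0.969 by nearest start. In the 275 highest peaks the cell cycle and repair lists had odds ratios of 0, and with 3000 pooled peaks muscle had 1.72 and neurons 1.67. What the unknown depth limits was not tested.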

Other observations

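All tests in this part were chosen after the peaks had been seen. What would count for or against each explanation was set before the values were computed for E2F sites at ribosomal protein promoters and for the recruitment motif, repeats and multi-copy sequence on X, and after they were seen for transcription and for mitochondrial coverage. For repeats the median did not fall under the 20% set beforehand as counting against them. Nor did it reach the 50% set beforehand for them, so that test is undecided.

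Gene name classes with at least 5 members were tested by Fisher's exact test, and 9 of 419 passed an adjusted p of 0.05: rpl, rps, hcp, mcm and the following. Of 6 eef genes, which encode translation elongation factors, 4 were bound (adjusted p = 0.0012, exact test), led by eef-2 (I:9163416-9163668, signal 136). All 4 eef peaks lay in the window of another gene too: clsp-1 for eef-2, rfc-4 for eef-1A.1, ctf-4 for eef-1G and aco-2 for eef-1B.1. Of 8 rsp genes, encoding SR splicing proteins, 4 were bound through 3 peaks (adjusted p = 0.0039, exact test), and of 7 snr genes, encoding core spliceosomal Sm proteins, 3 were (adjusted p = 0.0406, exact test). The rsp-1 and rsp-2 peak had a signal of 50.8, and rsp-5 and snr-3 shared a peak. Of 15 cox genes, nuclear genes of cytochrome c oxidase and its assembly, 4 were bound (adjusted p = 0.0406, exact test), led by cox-5A (III:12905079-12905300, signal 114). Of 8 cct genes of the cytosolic chaperonin, 3 were bound (adjusted p = 0.0495, exact test), with cct-8 at a signal of 85.1. Classes that came close without passing included vps (5 of 31, adjusted p = 0.0568), mdt (4 of 20, adjusted p = 0.0689) and hsp (4 of 22, adjusted p = 0.0854, exact tests).

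Small noncoding RNA genes were another group at the summits. They were compared with the other 29446 nuclear lines of the pooled list, which holds background as well as peaks. A snoRNA gene, whose product guides RNA modification, lay within 100 bp of 25 of the 523 nuclear summits (4.78%), against 0.343% of those lines (odds ratio 14.6, 95% interval 8.93 to 23.0, Fisher's exact test, adjusted p = 6.0e-19). Of these 25 peaks, 17 were outside promoter windows of protein-coding genes. Genes annotated as snRNA, which include the spliced leader genes sls-2.1, sls-2.4 and sls-2.8, lay at 8 summits (odds ratio 12.02, exact test, adjusted p = 1.8e-06). A pair of these were overlapping peaks at sls-2.1; with overlapping peaks counted once, 7 of 519 remained (odds ratio 12.7, exact test, adjusted p = 6.5e-06). The strongest was at sls-2.1 (II:5844659-5845014, signal 96.3). Genes for tRNA lay at 13 summits (2.49% against 1.02%, odds ratio 2.47, exact test, adjusted p = 0.0038), and 8 of these were among the 27 X peaks outside promoters.

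Peaks at ribosomal protein promoters were frequent (22 of 78 genes) and among the strongest. The muscle, intestine, cuticle and sperm protein lists had 0 of 75 genes bound, with an upper bound of 4.80%. That lies below the lower bound of 18.6% for ribosomal protein genes. It does not decide whether any strongly transcribed gene of the worm gives a peak. No expression values were used to choose these lists, the fusion is under a germline promoter, and the mark was set after the counts were seen. Binding through E2F-like sites stays open: TTSSCGC was in 4 of 21 peaks (19.05%) against 8.57% of GC-matched controls (Fisher's exact test, p = 0.229), and 31.1% of other promoter peaks had it, so 21 peaks are too few to decide against either. It was rarer than at DREAM, replication and mitosis promoter peaks. With the peak shared by rpl-12 and lin-54 left out, 3 of 20 had it against 16 of 23 (Fisher's exact test, adjusted p = 8.3e-04 over 3 strings). Strong transcription in the germ line alone may also be a cause and was not tested, since these files hold no expression values. Regions that many unrelated factors appear to occupy stay open too, as no peaks of another factor were used here, and no second group tests a biological explanation.

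Mitochondrial DNA gave 27 thresholded peaks, 13 of them among the highest 20, although LIN-35 is a nuclear protein. Together they covered 70.5% of the 13794 bp mitochondrial genome, and the mitochondrial peaks in the highest 550 of replicates 1 and 2 covered 77.7% and 61.6%. The same 27 intervals placed at random covered a median of 64.01% (54.2% to 73.2% in 95% of 10000 draws), so their number and widths alone set the coverage and the test decides nothing. Uneven coverage of a molecule present in many copies per cell and binding cannot be told apart here, because the files hold no read depth along this genome, and no biological explanation was tested.

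X chromosome peaks outside promoters may in part mark sites that load the dosage compensation complex, a condensin-like complex that acts on both X chromosomes of hermaphrodites. GCGCAGGG, the core of the motif of those sites, was in 10 of 27 such windows (37.0%) and 0 of 115 autosomal ones (Fisher's exact test, p = 1.3e-08). It was in 12 of 32 against 1 of 112 from replicate 1's own highest peaks and 6 of 24 against 0 of 174 from replicate 2's. The whole chromosome had 4.57 per Mb against 2.82 on autosomes. The string was also in 2 of 9 X promoter windows (22.2%), so it was not particular to X peaks outside promoters. Multi-copy sequence over most of a window is argued against, since 0% of these windows had over 50% of their 36-mers elsewhere in the genome (upper bound 12.8%). A shorter multi-copy stretch, such as a tRNA gene, could not reach that mark and was not tested. Repeats as the main cause are argued against too, with a median of 22.9% soft-masked bases (95% exact interval 9.95 to 30.3). The median was 19.4% in autosomal non-promoter and 33.8% in nuclear promoter windows. Of the other 17 windows 8 were at a tRNA gene (29.6% of the 27 against 2.61% on autosomes, Fisher's exact test, p = 7.3e-05), where X holds 45.1% of nuclear tRNA genes, and 9 had neither. Whether LIN-35 binds there or the open chromatin of such sites is recovered in any ChIP was not tested. The fusion is under a promoter used in the germ line, and germ line and soma were not separated, so the tissue of these peaks is unknown.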
